A study of Mus musculus with 16 samples.

How the data were processed

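RNA from mouse testis was split with J2, a monoclonal antibody that binds double-stranded RNA. The RNA captured by the antibody (J2) and the RNA left in the supernatant (flow-through) were sequenced separately. The 16 libraries fall into 6 groups: wild-type testis at postnatal day 18 (P18), testis labelled Dicer knock-out at P18, and adult testis, each as J2 and as flow-through. There were 3 libraries in each P18 group and 2 in each adult group. Per the labels' protocols, the libraries were made with a strand-specific low-input kit (NuGEN Ovation SoLo), and the flow-through libraries are described as depleted of ribosomal and double-stranded RNA. A mixed C57BL/6 and 129S4/SvJae background is stated for the P18 mice and no strain for the adults, so age and strain cannot be separated. The labels give a code that one flow-through and one J2 library share, and do not state that replicates came from separate animals. The p-values below therefore measure the spread between these samples, which may be technical.

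The submitters' processing notes name FastQC (read quality), Trimmomatic (trimming), Salmon (transcript quantification), DESeq2 (normalization and testing of counts) and the genome build mm10. The notes give no version or setting, and the roles in parentheses are what these tools are generally used for. The deposited values are a signal on a normalized count scale, made by the authors, with 1 value per Ensembl gene and library for 35920 genes. Of the gene identifiers, 35446 matched a symbol and 474 did not. Every column was matched to a library by its label (0 left over), and 0 pairs of columns were identical. Coordinates come from an annotation of GRCm38.p6, the assembly that mm10 names.

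Values at multiples of 1 read were found for 16 to 94 genes per library, and for 4237 in adult J2 replicate 2. Whole reads could therefore not be recovered across the libraries, and the planned count test on recovered reads was not run. The worth of 1 read in each library was approximated as the value that several genes share and whose multiples other genes also hold (up to 20 multiples, tolerance 1e-06). It was 2 to 8.31 units in the flow-through libraries and 0.116 to 0.516 in the J2 libraries. The column totals were 6.054 to 34.86 M units (M, 1e+06) in flow-through and 0.446 to 0.824 M units in J2. They correspond to about 0.998 to 5.87 M reads and 1.23 to 4.54 M reads. A value of 10 therefore stands for about 1.2 to 5 reads in flow-through and 19 to 86 reads in J2, so a value of 0 in flow-through is a weaker statement than a value of 0 in J2. The authors' scaling sets the median gene about equal between fractions. Rescaling each library to a common total over genes other than the mitochondrial ones (set to 1e+06) moved the median log2 difference of all genes between J2 and flow-through from -0.05 to 1.87 in wild-type P18, from -0.15 to 2.16 in knock-out P18 and from 0.05 to 2.74 in adults. All J2 against flow-through changes are therefore relative to the median gene, and not amounts of RNA. The 10 highest features held 95.75% to 98.83% of the signal in flow-through and 43.61% to 67.51% in J2. The common total therefore depends largely on these features, among them AY036118, which was listed at 0 in all J2 libraries. Results after rescaling show this dependence and are no neutral check of a call. On log2(value + 1) the rescaling moves low genes less than high ones, so the median of all genes understates its shift of high genes. The same rescaling moved the median from 0.33 to -0.12 for knock-out against wild type in flow-through, from 0.13 to 0 in J2, from 0.28 to -0.21 for adult against P18 in flow-through and from 0.33 to 0.48 in J2, and from 0.06 to 0.73 for the age by fraction interaction.

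Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean trend) and Benjamini-Hochberg adjustment, two-sided, with a threshold of 0.05. Log2 changes are on that scale, which understates the change of low genes. Genes needed a value of 10 in at least 2 of the libraries fitted. J2 against flow-through (within wild type, knock-out and adult) and the 2 interactions (genotype by fraction, age by fraction) were fitted over all 16 libraries. Knock-out against wild type and adult against wild type at P18 were fitted within each fraction over its 8 libraries. Gene lists with at least 3 measured members were tested with camera (limma) at a preset correlation of 0.01, and again with an estimated correlation. The shares of the signal taken by mitochondrial genes and by the 10 highest genes were compared by a two-sided exact permutation test where both groups had 3 libraries, a design in which p cannot go below 0.1.

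The tests, the samples entering each fit, 30 gene lists and the rule for named genes were fixed before the data were examined. The lists cover mitochondrially encoded heavy-strand mRNAs, the light-strand mRNA with the mitochondrial rRNAs, nuclear respiratory chain subunits, mitochondrial RNA turnover, small RNA biogenesis, proteins that bind or edit double-stranded RNA, sensing of double-stranded RNA, interferon-stimulated genes, the piRNA pathway, spermatogonia, meiotic prophase, pachytene spermatocytes, round spermatids, elongating spermatids, Sertoli, Leydig and peritubular myoid cells, macrophages, endothelium, red blood cells, the Speer family, multicopy sex chromosome genes, the Rhox cluster, small nucleolar, Cajal body and spliceosomal RNAs, imprinted and long noncoding RNAs, immediate-early genes, cytosolic ribosomal proteins, replication-dependent histones, opposite-strand RNAs and their host genes. The rule for named genes took, among called genes with a mean of at least 50 whose groups did not overlap, the 12 largest rises and the 12 largest falls, without predicted genes and pseudogenes. It also took up to 4 called members of each list, and Dicer1 and the mitochondrial mRNAs whatever their result. For an interaction the number was 6 each way. The text uses fewer where names repeat. A result for 1 gene is not reported here.

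The shared codes were used as a block in an alternative fit, because a code shared by a flow-through and a J2 library was taken to mark 1 split sample. The deviations of the 8 pairs from their group means correlated between -0.083 and 0.043 over 3363 genes, with 0 of 8 above 0.1, and 4 of 8 libraries correlated best with their own partner. The adult pairs A1 and A2 necessarily share the same correlation (0.037), because deviations from a mean of 2 libraries mirror each other. They are therefore not separate results. Further alternatives were a pseudocount of 5, no filter, the rescaling to a common total, quantile normalization, only the groups compared, all 16 libraries in the fits within a fraction, library weights by fraction, a filter at 50 and leaving out each library in turn. The gene set was kept when a library was left out and in the rescaling to a common total. The filter at 50 and the block were chosen after the data were seen.

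The scripts were tested on simulated data, negative binomial draws with the means and read values of these libraries. The dispersion of each gene was set to the median of genes of similar level, over both fractions. Genes more variable than that were not simulated, so false calls from such genes are not covered. For J2 against flow-through, 4-fold changes were recovered in 4.04% (wild type, 9566 genes), 3% (knock-out, 9503 genes) and 1.02% (adult, 9639 genes) of the changed genes, and 16-fold changes in 39%, 29% and 19.2%. For knock-out against wild type the shares were 1% and 33% in J2 (6876 genes), and 0% and 4% in flow-through (7042 genes). For adult against P18 they were 5.15% and 57% in J2 (7042 genes), and 0% and 13% in flow-through (7118 genes). In 20 simulations without any change, J2 against flow-through still called a median of 2.5 genes (at most 10) in wild type, 2 (at most 11) in knock-out and 27 (at most 47) in adults. The cause was not tested. Among genes with a mean of at least 50, the simulations without change called at most 0, 0 and 3. They called at most 1, 0 and 2 lists for J2 against flow-through, and at most 1 in any other comparison. Genes were drawn independently, so these simulations cannot show how many lists are called when members are correlated (estimated at 0.581 for heavy-strand mRNAs). Regrouping the real libraries, described below, gave up to 5 lists. In the simulations with changes, 15, 15 and 34 unchanged genes were called. A shifted ribosomal protein list was recovered in all 7 comparisons.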

Results

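RNA from mouse testis was separated with J2, an antibody to double-stranded RNA, and the bound RNA (J2) and unbound RNA (flow-through) were sequenced in 16 libraries. Wild-type testis at postnatal day 18 (P18, when most germ cells are in meiosis) and testis labelled Dicer knock-out at P18 gave 3 libraries per fraction, and adult testis gave 2 per fraction. Dicer is the RNase that cuts long double-stranded RNA and microRNA precursors. The files hold the authors' normalized counts, whose sums were 6.054 to 34.86 M units (M, 1e+06) in flow-through and 0.446 to 0.824 M units in J2. Values of at least 10 were found for 3598 to 4688 genes per flow-through library and 3492 to 4950 per J2 library. Replicates of a group correlated modestly over 3363 genes (Spearman's rho across genes, which are not independent replicates, 0.35 to 0.6).

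A few features took most of the flow-through signal. The 10 highest features held 96.5% ± 0.735 (SD, n = 3) of it in wild-type P18 flow-through and 54.6% ± 11.2 (SD, n = 3) in wild-type J2 (two-sided exact permutation test p = 0.1, the smallest this design allows). In the knock-out they held 97.1% ± 1.48 and 66.7% ± 0.911 (SD, n = 3 each, exact permutation p = 0.1), and in adult J2 51.9% (n = 2, no test). In flow-through the leading features were Gm42418 (9.9% to 60.4% of a library) and AY036118 (8.38% to 16.7%). AY036118 is a noncoding transcript on chromosome 17 at 39848112 to 39898385 (mm10) whose start overlaps the end of the ribosomal RNA pseudogene Rn18s-rs5. Lars2, the mitochondrial leucyl-tRNA synthetase gene on chromosome 9 at 123366927 to 123462675, took 1.33% to 70.6%. Its highest shares were in knock-out flow-through replicate 1 (61.4%) and adult flow-through replicate 2 (70.6%). Whether the reads assigned to Lars2, here and in the comparisons below, came from its mRNA or from ribosomal RNA was not tested. AY036118 was listed at 0 in all 8 J2 libraries, where Gm42418 held 0.128% to 1.47%. Whether AY036118 was left out of the J2 quantification could not be checked, so its fall may not be a measured one. In J2 the leading feature was CT010467.1, with 37.9% to 62.4% of the signal against 0.408% to 8.09% in flow-through. Neither CT010467.1 nor Gm42418 had coordinates in the annotation used, and whether their reads came from ribosomal RNA was not tested. The share of CT010467.1 therefore does not show how much of the J2 signal was double-stranded RNA.

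**Figure D1:**
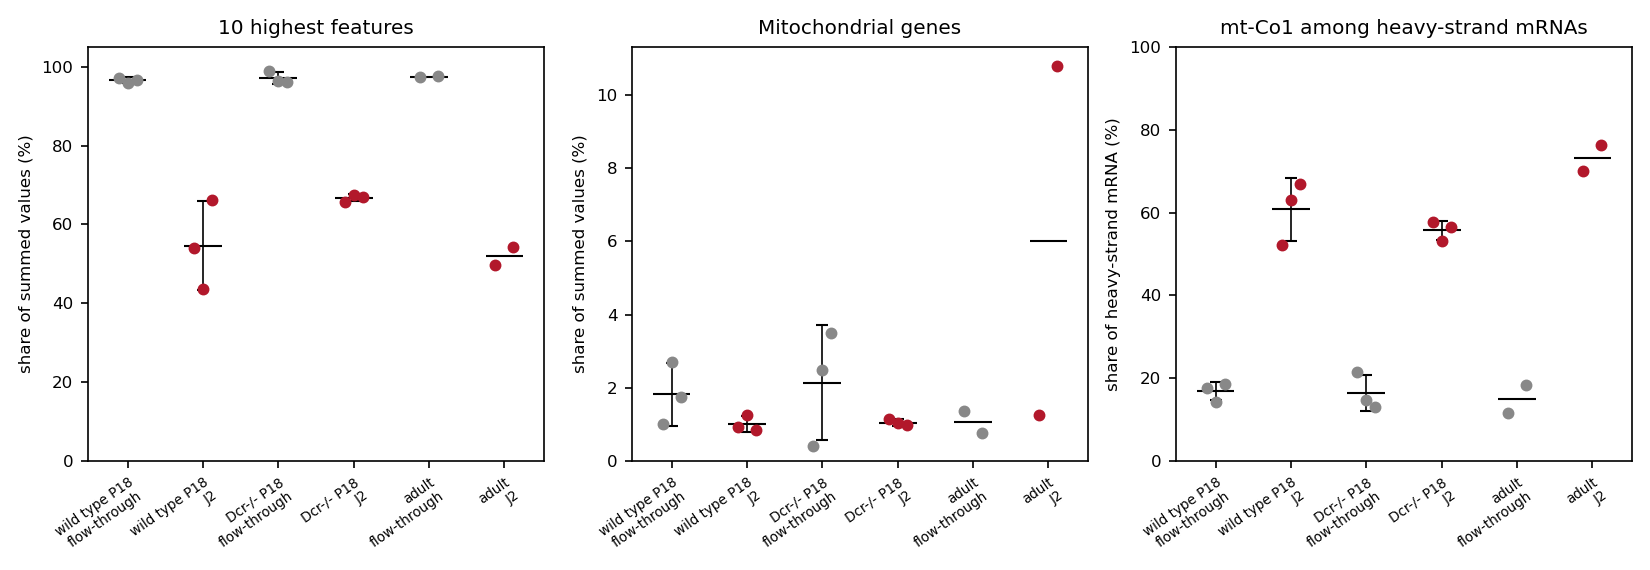
Share of each library's summed normalized values held by its 10 highest features (left) and by mitochondrial genes (middle), and share of the mitochondrial heavy-strand mRNA held by mt-Co1 (right), all in percent, by group. Points are libraries, horizontal lines are group means and bars are the SD of groups of 3; the 10 highest features held 95.75% to 98.83% in flow-through and 43.61% to 67.51% in J2, mt-Co1 held 11.6% to 21.4% and 52.2% to 76.2%, and adult J2 replicate 2 had a mitochondrial share of 10.8%.

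Dicer1, the targeted gene (chromosome 12, 104687740 to 104751968), was too low in every group to check the knock-out. It was listed at 0 in 7 of the 16 libraries and reached at most 13.7 normalized counts. In J2 the 3 wild-type libraries had 11.3, 0 and 8.64 and the 3 libraries labelled knock-out 3.39, 0 and 0, a log2 difference of -1.58 (SE 1.28, limma adjusted p = 0.91). In flow-through the values were 5.1, 12.4 and 0 in wild type and 0, 3.68 and 8.33 in the knock-out, below the level needed for a test. The adult libraries had 0 and 3.9 in flow-through and 0 and 13.7 in J2.

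The comparison of J2 with flow-through asks which transcripts are enriched by the antibody. In wild-type P18 testis, mRNAs of cytosolic ribosomal proteins, small nucleolar and spliceosomal RNAs and nuclear respiratory chain mRNAs were higher in J2 as lists, relative to the median gene, while most of their members did not pass singly. The lists of mitochondrial RNAs were lower. With an estimated correlation the small nucleolar RNA (adjusted p = 0.21) and heavy-strand (adjusted p = 0.39) calls were lost. Of 82 measured ribosomal protein mRNAs 10 rose (33 adjusted over the list alone) and 0 fell, with a median log2 change of 1.90 (camera adjusted p = 4.3e-17, and 0.022 with an estimated correlation). Rps15 was at 309 ± 140 in J2 and 6.41 ± 1.56 in flow-through (SD, n = 3 each, log2 change 5.31, SE 0.78, adjusted p = 0.0012). Respiratory chain subunits encoded in the nucleus had a median of 1.29 (adjusted p = 4.1e-05, and 0.022 with an estimated correlation), with 1 of 26 rising (6 adjusted over the list alone). This was Cox6c of cytochrome c oxidase, at 198 ± 31.7 against 1.89 ± 3.28 (SD, n = 3 each, log2 change 6.71). Small nucleolar, Cajal body and spliceosomal RNAs had a median of 2.16 (adjusted p = 9.1e-08, but adjusted p = 0.21 with an estimated correlation), with 3 of 45 rising (5 adjusted over the list alone). Among them was Snord118, the U8 RNA of ribosome maturation, at 226 ± 131 against 5.2 ± 9.01 (SD, n = 3 each, log2 change 6.29). Its call ended without wild-type J2 replicate 2 (5.86, adjusted p = 0.051). Of the 164 members of this RNA list, 44 passed the filter within the J2 libraries and 26 within flow-through. Part of the list was thus tested because of its J2 values, so its median and call are partly fixed by the filter. Ribosomal protein mRNAs had a median of 1.51 after quantile normalization, and of 5.09 after rescaling to a common total, where the median of all genes was 1.87. That median includes low genes, which the rescaling moves less, so the distance between these medians is no measure of enrichment. Psmb1, a proteasome subunit, rose by 4.85 (251 ± 39.8 against 10.2 ± 8.98, SD, n = 3 each). That call ended without flow-through replicate 1 (4.17, adjusted p = 0.08) or J2 replicate 2 (4.81, adjusted p = 0.051). Ldhc, the lactate dehydrogenase of germ cells, rose by 2.40 (863 ± 423 against 153 ± 32.7, SD, n = 3 each) and Hist1h4i, a histone H4 gene, by 4.12 (575 ± 134 against 32.4 ± 8.99). Both calls ended whichever of the 6 libraries was left out (2.03 to 2.67 and 3.88 to 4.28). Replication-dependent histones had a median of 0.62 (adjusted p = 0.022, but adjusted p = 0.83 with an estimated correlation). Of these, 1 of 58 rose (1 adjusted over the list alone). That list call ended without flow-through replicate 2 (0.34, adjusted p = 0.71) or J2 replicate 2 (0.22, adjusted p = 0.68), after quantile normalization (0.35, adjusted p = 0.19) and with a filter at 50 (0.66, adjusted p = 0.22). With the shared codes as a block the calls of Cox6c (adjusted p = 0.054), Psmb1 (0.078), Hist1h4i (0.12) and Ldhc (0.11) ended.

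Among RNAs that fell in wild-type J2, the mitochondrial 12S and 16S rRNAs mt-Rnr1 and mt-Rnr2 (mitochondrial positions 70 to 1024 and 1094 to 2675) were at 1360 ± 367 against 59100 ± 13700 and 1400 ± 408 against 72600 ± 16300 (SD, n = 3 each, log2 changes -5.45 and -5.72, adjusted p = 6.4e-07 and 5.3e-05). Neither was called after rescaling to a common total (-1.49 and -1.76) or quantile normalization (0 and -0.53). In their list with the light-strand mRNA mt-Nd6, 2 of 3 fell (2 adjusted over the list alone). The median was -5.45 (adjusted p = 8.5e-07, and 0.033 with an estimated correlation), but -1.49 (adjusted p = 0.12) after rescaling to a common total and -0.53 (adjusted p = 0.68) after quantile normalization. The heavy-strand mRNAs had a median of -2.47 (adjusted p = 2e-05, but adjusted p = 0.39 with an estimated correlation), which became 1.17 (adjusted p = 0.53) after rescaling to a common total, still below the 1.87 of all genes there. Of these 12 mRNAs 3 fell (6 adjusted over the list alone): mt-Nd4 (-5.81), mt-Cytb (-4.58) and mt-Nd1 (-3.00). The mt-Nd1 change became 0.95 after that rescaling. All 3 calls ended without flow-through replicate 2 (-5.40, -4.14 and -2.82) or replicate 3 (-6.10, -4.46 and -3.11) or J2 replicate 2 (-4.57, -4.36 and -2.56). Those of mt-Cytb and mt-Nd4 also ended without J2 replicate 1 (-4.08 and -5.82), and those of mt-Nd4 and mt-Nd1 without flow-through replicate 1 (-5.92 and -3.07). Mitochondrial mt-Co1 was at 1390 ± 579 against 859 ± 248 (SD, n = 3 each, log2 change 0.65, adjusted p = 0.73). The features annotated as microRNA loci, Mir6236 (79.2 ± 43.5 against 594000 ± 193000, SD, n = 3 each, log2 change -12.94) and Mir6240 (152 ± 88.8 against 572000 ± 356000, log2 change -11.93), fell furthest of the named genes with signal in both fractions. Whether their reads came from microRNAs or from ribosomal RNA was not tested. Lars2 fell by 6.15 (6590 ± 1240 against 629000 ± 618000, SD, n = 3 each), which turned to a rise of 1.51 (adjusted p = 0.61) after quantile normalization. Its call ended without flow-through replicate 1 (-6.44) or 3 (-5.38) or without any 1 of the J2 libraries (-6.25 to -5.98). The mitochondrial genes together held 0.999% ± 0.215 of the J2 signal and 1.82% ± 0.857 of flow-through (SD, n = 3 each, two-sided exact permutation p = 0.2). This difference of -0.816 points became -39.2 points without the 10 highest other genes.

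With limma over 9526 genes, 50 rose and 36 fell in wild-type J2, against 2562 and 13 after rescaling to a common total, and 7 and 17 with the shared codes as a block. The rescaled counts depend on the few features that hold most of the flow-through signal. Simulations without any change called at most 10 genes. In the real data 44 of the called genes had a mean of at least 50, where the simulations called 0. The simulations held no genes more variable than the median of their level, so this 0 may be too low a reference. The count of rises was 12 without flow-through replicate 1, 14 without replicate 3, and 24, 10 and 32 without J2 replicates 1, 2 and 3. That of falls was 15 and 16 without flow-through replicates 1 and 3 and 17 and 15 without J2 replicates 1 and 2. Histone, ribosomal protein and U3 genes have near-identical copies or pseudogenes, so their values depend on how reads were divided.

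In knock-out P18 testis 5 lists were called, all among those of wild type, but 0 with an estimated correlation, and another split of the libraries also gave 5. The small nucleolar, Cajal body and spliceosomal RNAs had a median log2 change of 1.75 in J2 (camera adjusted p = 1.3e-10, but adjusted p = 0.096 with an estimated correlation). Of these, 6 of 45 rose (12 adjusted over the list alone). As in wild type, part of this list was tested because of its J2 values, so the call is partly fixed by the filter. Snord118 was at 124 ± 50.1 in J2 and 2.89 ± 2.5 in flow-through (SD, n = 3 each, log2 change 5.27, adjusted p = 0.036). Snora24, which guides pseudouridylation, was at 62.6 ± 27.3 in J2 (SD, n = 3) and listed at 0 in flow-through (adjusted p = 0.0099; 0.075 and 0.061 without J2 replicates 2 and 3). The U3 genes Rnu3b2 and Rnu3b4 had the same value, 93.4 ± 41.9 in J2 (SD, n = 3), and were listed at 0 in flow-through. Their calls ended whichever library was left out (6.14 to 6.83). Ribosomal protein mRNAs had a median of 1.28 (adjusted p = 2.8e-13, but adjusted p = 0.052 with an estimated correlation), with 3 of 82 rising (19 adjusted over the list alone). These were Rps15 (134 ± 71.2 against 7.47 ± 1.78, log2 change 3.82), Rps3 (152 ± 36.7 against 11.4 ± 5.27, 3.67) and Rps24 (406 ± 279 against 36.5 ± 30.7, 3.54; SD, n = 3 each). Nuclear respiratory chain mRNAs had a median of 0.92 (adjusted p = 0.0054, but adjusted p = 0.096 with an estimated correlation), and 1 (adjusted p = 0.055) without J2 replicate 2. The call also ended after quantile normalization (0.93, adjusted p = 0.071) and with a filter at 50 (0.92, adjusted p = 0.23). Of these, 0 of 26 were called (1 rise and 1 fall adjusted over the list alone). The mitochondrial rRNAs fell, mt-Rnr1 by 5.31 (1730 ± 140 against 70500 ± 18900) and mt-Rnr2 by 5.93 (2050 ± 484 against 127000 ± 42000; SD, n = 3 each), but had log2 changes of 0.77 and 0.80 after quantile normalization, and were not called after rescaling to a common total. Their list had a median of -5.31 (adjusted p = 8.8e-05, but adjusted p = 0.096 with an estimated correlation), which turned to 0.79 (adjusted p = 0.32) after quantile normalization. After rescaling to a common total it was -1.07 (camera adjusted p = 0.23), where all genes had a median of 2.16. In it 2 of 3 fell (2 adjusted over the list alone). The heavy-strand mRNAs had a median of -2.22 (adjusted p = 0.0038, but adjusted p = 0.57 with an estimated correlation), and 1.94 (adjusted p = 0.94) after rescaling to a common total, below the 2.16 of all genes there. Of these, 0 of 12 were called (6 falls adjusted over the list alone). Kat6b, a histone acetyltransferase gene, fell by 5.90 (0.91 ± 0.896 against 131 ± 99.1, SD, n = 3 each). The call ended without flow-through replicate 3 (-5.30, adjusted p = 0.063) and after rescaling to a common total (-2.26, adjusted p = 0.12). Lars2 fell by 6.53 but had a log2 change of 0.70 after quantile normalization, and its call ended without any 1 of the J2 libraries (-6.56 to -6.49). Mitochondrial genes held 1.05% ± 0.0871 of the J2 signal and 2.13% ± 1.57 of flow-through (SD, n = 3 each, exact permutation p = 0.4), a difference of -1.08 points that became -44.8 points without the 10 highest other genes.

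Of 9526 genes, limma called 16 higher and 18 lower in knock-out J2 (42 and 22 after quantile normalization, 2848 and 15 after rescaling to a common total, 4 and 16 with the block). Simulations without change called at most 11. The count of rises was 4 without any 1 of the flow-through libraries, and 5 and 6 without J2 replicates 2 and 3. The calls of Rps3 and Snord118 ended whichever of the 6 libraries was left out (3.45 to 3.99 and 4.47 to 5.68). That of Rps15 ended in all cases but J2 replicate 1 (3.53 to 3.98) and that of Rps24 without flow-through replicates 1 and 2 or J2 replicates 2 and 3 (3.07, 3.38, 3.73 and 3.02). With the block the calls of Snord118 (adjusted p = 0.11), Snora24 (0.083), Rps15 (0.14), Rps3 (0.11) and Rps24 (0.068) ended. Between genotypes, 8 rises (0.084 for independent lists) and 15 falls (0.068) were shared. Both comparisons use different libraries, but the same fit over all 16 libraries gave each gene a common variance. Their calls are therefore not independent, and the numbers for independent lists are only a reference.

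In adult testis the ribosomal protein and small nucleolar RNA lists were not called in J2 against flow-through (medians 0.24 and 0.42). Rnf133, a testis ubiquitin ligase gene, was at 336 ± 184 in J2 and 5.48 ± 2.01 in flow-through (SD, n = 2 each, log2 change 5.62, adjusted p = 0.0081). Cntnap5b, a neurexin family gene, was at 231 ± 266 and 2.71 ± 0.312 (SD, n = 2 each, log2 change 5.19, adjusted p = 0.021; 5.10 with adjusted p = 0.095 without flow-through replicate 1). BC061195 was at 112 ± 125 in J2 (SD, n = 2) and listed at 0 in flow-through. With only the adult libraries fitted these 3 calls ended (adjusted p = 0.051, 0.48 and 0.6), and with the block those of Rnf133 and Cntnap5b (0.07 and 0.092). Replication-dependent histones had a median of -1.48 (camera adjusted p = 4.9e-10, but adjusted p = 0.86 with an estimated correlation), with 0 of 58 called (2 falls adjusted over the list alone). Simulations without change called up to 2 lists in adults, so this single list call does not exceed them. The median became 1.88 (adjusted p = 0.27) after rescaling to a common total, below the 2.74 of all genes there, and was -0.61 (adjusted p = 0.4) without J2 replicate 2. The 13 genes that fell in all 3 comparisons included Lars2, mt-Rnr1, AA474408, Gm42418, Mir6240, Mir6236 and AY036118, whereas 0 rises were shared by all 3. The adult call of Lars2 ended whichever of the 4 libraries was left out (-10.18 to -7.13). That of AA474408 ended without flow-through replicate 2 (-7.67, adjusted p = 0.084) or J2 replicate 1 (-9.01, adjusted p = 0.086). The adult change of mt-Rnr1 was -3.85 (4120 ± 3520 against 47400 ± 519, SD, n = 2 each), becoming 0.75 after rescaling to a common total (2.74 for all genes) and turning to 1.49 after quantile normalization. Its call ended without flow-through replicate 1 (-3.86, adjusted p = 0.059) or J2 replicate 1 (-2.84, adjusted p = 0.083). Mitochondrial genes held 6.04% of the J2 signal and 1.06% of flow-through (n = 2 each, no test), a difference of 4.97 points that turned to -24.8 points without the 10 highest other genes. In J2 replicate 2 the share was 10.8% and in replicate 1 1.24%.

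The limma counts in adults were 14 higher and 16 lower of 9526 (26 and 17 after quantile normalization, 3460 and 11 after rescaling, 2 and 13 with the block). Simulations without change reached 47 calls, so these counts do not exceed them. Of the called genes 17 (4 rises and 13 falls) had a mean of at least 50, where the simulations reached 3 in both directions together. The 4 rises thus lie near that number. As the simulations lacked genes of high spread, 3 may be too low a reference. The rises numbered 7 and 74 without flow-through replicates 1 and 2 and 36 without J2 replicate 2, and the falls 44 without J2 replicate 2.

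**Figure D2:**
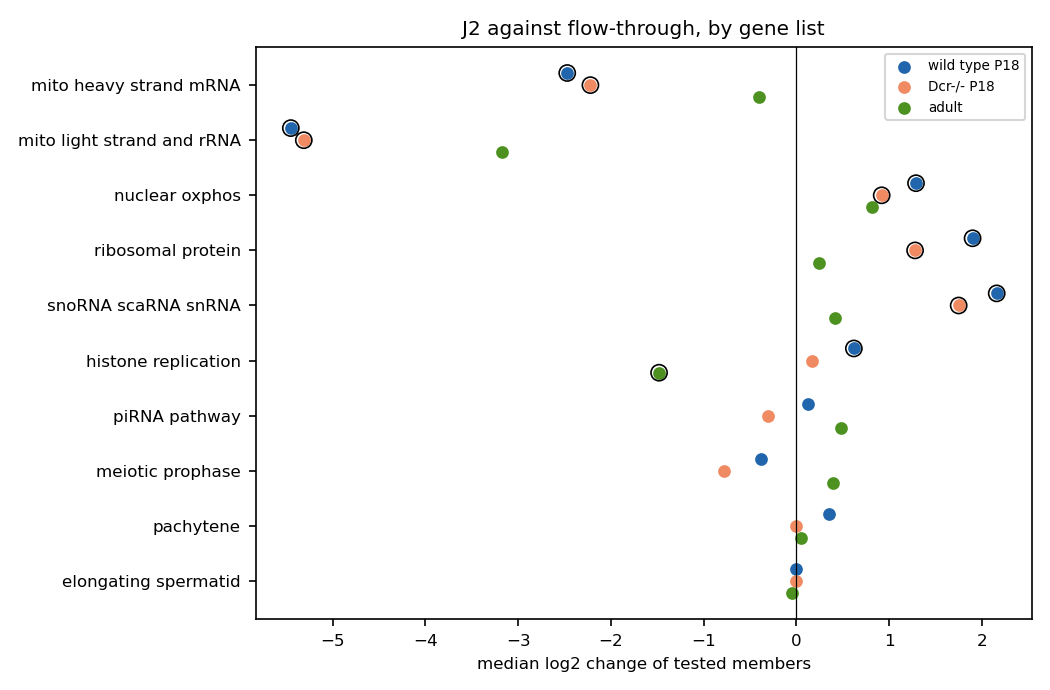
Median log2 change (J2 against flow-through) of the tested members of 10 gene lists in wild-type P18, knock-out P18 (Dcr-/-) and adult testis; encircled points had a camera adjusted p under 0.05. Ribosomal protein mRNAs lay at 1.90, 1.28 and 0.24, and heavy-strand mitochondrial mRNAs at -2.47, -2.22 and -0.40, which became 1.17 in wild type and 1.94 in the knock-out after rescaling to a common total, where all genes had medians of 1.87 and 2.16.

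Knock-out was compared with wild type at P18 within each fraction, which asks whether loss of Dicer changes the double-stranded or remaining RNA. No single gene passed the test. In J2, limma called 0 of 6882 genes in either direction (440 at an unadjusted p under 0.05, smallest adjusted p 0.63). In flow-through it called 0 of 7141 (436, smallest adjusted p 0.28). The libraries of both groups did not overlap for 9.9% of genes in J2 and 10.6% in flow-through. Chance gives 10% for genes without tied values. Genes at 0 in most of these libraries cannot separate, so chance gives less than 10% over all genes. How far the observed shares exceed it was not tested. Among lists, pachytene spermatocyte genes were lower in the knock-out in both fractions. Their medians were -0.51 in J2 (camera adjusted p = 0.02, but adjusted p = 0.44 with an estimated correlation) and -0.36 in flow-through (adjusted p = 0.014, but adjusted p = 0.82 with an estimated correlation). Of these, 11 of 15 members in J2 and 13 of 16 in flow-through had lower values and 0 were called (1 fall in J2 and 0 in flow-through adjusted over the list alone). Pgk2, the glycolytic kinase of late germ cells, was at 0.554 ± 0.557 in the knock-out and 20 ± 8.35 in wild type in J2 (SD, n = 3 each, adjusted p = 0.68). Ccna1, the meiotic cyclin, was at 0.131 ± 0.227 and 66.1 ± 109 (adjusted p = 0.74). In flow-through Adam3, a sperm surface protein gene, was at 10.8 ± 9.51 and 39.6 ± 12.7 (SD, n = 3 each, adjusted p = 0.79). In J2 Adam3 went the other way, at 29.2 ± 43 and 13.4 ± 10.6. Pgk2, Ccna1 and Adam3 were not called and are examples from outside the rule for named genes. Round spermatid genes had a median of -0.53 in flow-through (adjusted p = 0.014, but adjusted p = 0.82 with an estimated correlation; 9 of 13 lower, 0 called, 0 adjusted over the list alone). In J2 their median was 0 (adjusted p = 0.12). In J2 the 3 tested genes of the list for double-stranded RNA sensing had a median of 3.39 (adjusted p = 0.0029, but adjusted p = 0.44 with an estimated correlation; 0 called, 2 adjusted over the list alone). Mavs, the mitochondrial adaptor of RNA sensing, was at 12.9 ± 3.98 against 0.378 ± 0.655, Trim25 at 19.5 ± 12.2 against 1.08 ± 1.87 and Irf3 at 15 ± 12.5 against 1.64 ± 2.85 (SD, n = 3 each). The receptors of that list were too low in J2 for a test. Wild-type means of Mavs, Trim25 and Irf3 lay far below the filter value of 10, so they were tested largely because of their knock-out values. This list call is therefore partly fixed by the filter and is no evidence of a change. In flow-through the tested members were in part other genes (Dhx58, Mavs and Ddx58), with a median of 0.12 (camera adjusted p = 0.73). Interferon-stimulated genes in J2 had a median of -0.51 (camera adjusted p = 0.35). Sertoli cell genes, not called, had medians of 0.88 in J2 (9 of 11 positive) and 0.53 in flow-through (9 of 13 positive, 3 rises adjusted over the list alone). Of the 10 splits of these libraries, the real one included, 5 gave at least as many list calls in either fraction. The mitochondrial share of the signal was 1.05% ± 0.0871 in knock-out J2 and 0.999% ± 0.215 in wild-type J2 (SD, n = 3 each, exact permutation p = 0.7), and 2.13% ± 1.57 and 1.82% ± 0.857 in flow-through (p = 0.8). Without the 10 highest other genes these differences went from 0.0472 to 0.89 points and from 0.315 to 6.44 points. For genotype by fraction, 0 of 9526 genes (455 at an unadjusted p under 0.05, smallest adjusted p 0.94) and 0 of 27 lists were called.

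Each of these 4 list calls depended on single libraries and on the processing. The sensing list ended without wild-type J2 replicate 1 (3.05, adjusted p = 0.051) or 2 (3.05, adjusted p = 0.07). The pachytene list in J2 ended without wild-type replicate 1 (-0.93, adjusted p = 0.064), 2 (-0.41, adjusted p = 0.098) or 3 (-0.77, adjusted p = 0.06) or knock-out replicate 3 (-0.21, adjusted p = 0.16). In flow-through the pachytene call ended without wild-type replicate 2 (-0.08, adjusted p = 0.18) or knock-out replicate 1 (-0.20, adjusted p = 0.16). The round spermatid call ended without wild-type replicate 2 (0, adjusted p = 0.27) or 3 (-0.67, adjusted p = 0.055) or knock-out replicate 1 (-0.60, adjusted p = 0.062). The sensing list was not called without a filter (0.15, adjusted p = 0.14) or with all 16 libraries (2.69, adjusted p = 0.065), nor the pachytene list in J2 after quantile normalization (-0.42, adjusted p = 0.11). In flow-through neither list was called after rescaling to a common total (-0.60 and -0.57), with all 16 libraries (-0.30 and -0.22) or with a filter at 50 (-0.24 and -0.19), nor round spermatid genes without a filter (0, adjusted p = 0.19).

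Adult and P18 wild-type testis were compared within each fraction, a contrast of age in which strain may differ as well. Genes of elongating spermatids, which are formed after P18, rose in adults in both fractions. In J2 17 of 20 rose (17 adjusted over the list alone), with a median log2 change of 6.45 (camera adjusted p = 4.7e-23, and 0.0026 with an estimated correlation). In flow-through 13 of 19 rose (18 adjusted over the list alone), with a median of 6.28 (adjusted p = 7.7e-22, and 0.0098 with an estimated correlation). The protamines that package sperm DNA were among them. Prm1 (chromosome 16, 10796332 to 10796823) was at 365 ± 65 in adult J2 (SD, n = 2) and listed at 0 in P18 J2. In flow-through it was at 689 ± 234 (SD, n = 2) against 0.813 ± 1.41 (SD, n = 3, log2 change 8.79, SE 1.17, adjusted p = 0.0024). Prm2 was at 382 ± 346 against 0.0807 ± 0.14 in J2 (log2 change 8.10, adjusted p = 0.00077). In flow-through it was at 665 ± 190 against 2.37 ± 4.11 (log2 change 8.34, adjusted p = 0.0025; 0.096 and 0.068 without adult flow-through replicates 1 and 2). Akap4, a scaffold of the sperm tail, was at 514 ± 316 in adult J2 and listed at 0 in P18 J2. In flow-through it was at 362 ± 70.3 against 0.884 ± 1.53 (adjusted p = 0.0081; 0.057 without adult flow-through replicate 1). Tnp2, a transition protein, was at 205 ± 72.3 in adult J2 and Tnp1 at 136 ± 57.2 in adult flow-through (SD, n = 2), each listed at 0 in the same fraction at P18. Smcp, of the sperm mitochondrial capsule, was at 360 ± 210 against 0.248 ± 0.43 in J2 (log2 change 8.09, adjusted p = 8e-04). Of round spermatid genes 9 of 17 rose in J2 (9 adjusted over the list alone; median 3.61, adjusted p = 3.5e-09, and 0.014 with an estimated correlation). In flow-through 5 of 13 rose (8 adjusted over the list alone; median 3.49, adjusted p = 5.4e-06, but adjusted p = 0.32 with an estimated correlation). Lyzl6, a sperm lysozyme-like gene, was at 36.9 ± 19.8 in adult J2 (SD, n = 2) and listed at 0 in P18 J2.

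Replication-dependent histones were lower in adults. In J2 12 of 57 fell (27 adjusted over the list alone) and the median was -3.23 (adjusted p = 1.6e-24, but adjusted p = 0.22 with an estimated correlation). Examples are Hist1h2bb (8.27 ± 4.24, SD, n = 2, against 224 ± 90.7, SD, n = 3, log2 change -4.60, adjusted p = 0.0018) and Hist1h2ai (2.6 ± 0.723 against 184 ± 133, -5.45). In flow-through 1 of 56 fell (0 adjusted over the list alone), with a median of -1.06 (adjusted p = 5.1e-10, but adjusted p = 0.56 with an estimated correlation). Red blood cell genes had a median of -3.75 in J2 (adjusted p = 0.0016, but adjusted p = 0.24 with an estimated correlation; 1 of 4 fell, 2 adjusted over the list alone). In flow-through the median was -2.98 (adjusted p = 0.00017, but adjusted p = 0.32 with an estimated correlation; 2 of 3 fell, 2 adjusted over the list alone). Adult haemoglobin beta, Hbb-bs, was at 2.99 ± 0.0959 (SD, n = 2) against 124 ± 81.1 (SD, n = 3) in J2 (log2 change -4.76, adjusted p = 0.0056). Among the largest single falls were collagen genes of connective tissue, for which no list was tested. They included Col3a1 in J2 (1.51 ± 2.13 against 146 ± 113, log2 change -5.85) and flow-through (1.11 ± 0.241 against 192 ± 213, -5.88), and Col1a1 in flow-through (0.657 ± 0.93 against 95.1 ± 86.4, -5.55). Col1a1 (-5.11) and Col1a2 (-4.68) also fell in J2 and Col6a3 (-5.27) in flow-through. Ribosomal protein mRNAs had a median of -1.62 in J2 (adjusted p = 2.6e-16, but adjusted p = 0.1 with an estimated correlation; 4 of 81 fell, 5 adjusted over the list alone). It was -0.07 in flow-through, where the list was not called. In J2 peritubular myoid genes (-2.41, adjusted p = 0.008, but adjusted p = 0.33 with an estimated correlation; 0 of 5 called, 1 adjusted over the list alone) and Sertoli cell genes (-1.20, adjusted p = 0.031, but 0.22 with an estimated correlation; 0 of 11, 0 adjusted over the list alone) were lower as lists. So were respiratory chain subunits (-1.13, adjusted p = 0.0034, but 0.22; 0 of 26, 0 over the list alone) and small nucleolar RNAs (-0.67, adjusted p = 0.0071, but 0.51; 0 of 44, 0 over the list alone). Heavy-strand mRNAs (1.93, adjusted p = 0.039, but 0.75; 0 of 12, 0 over the list alone) and the light-strand and rRNA list (2.41, adjusted p = 0.045, but 0.33; 0 of 3, 2 over the list alone) were higher.

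**Figure D3:**
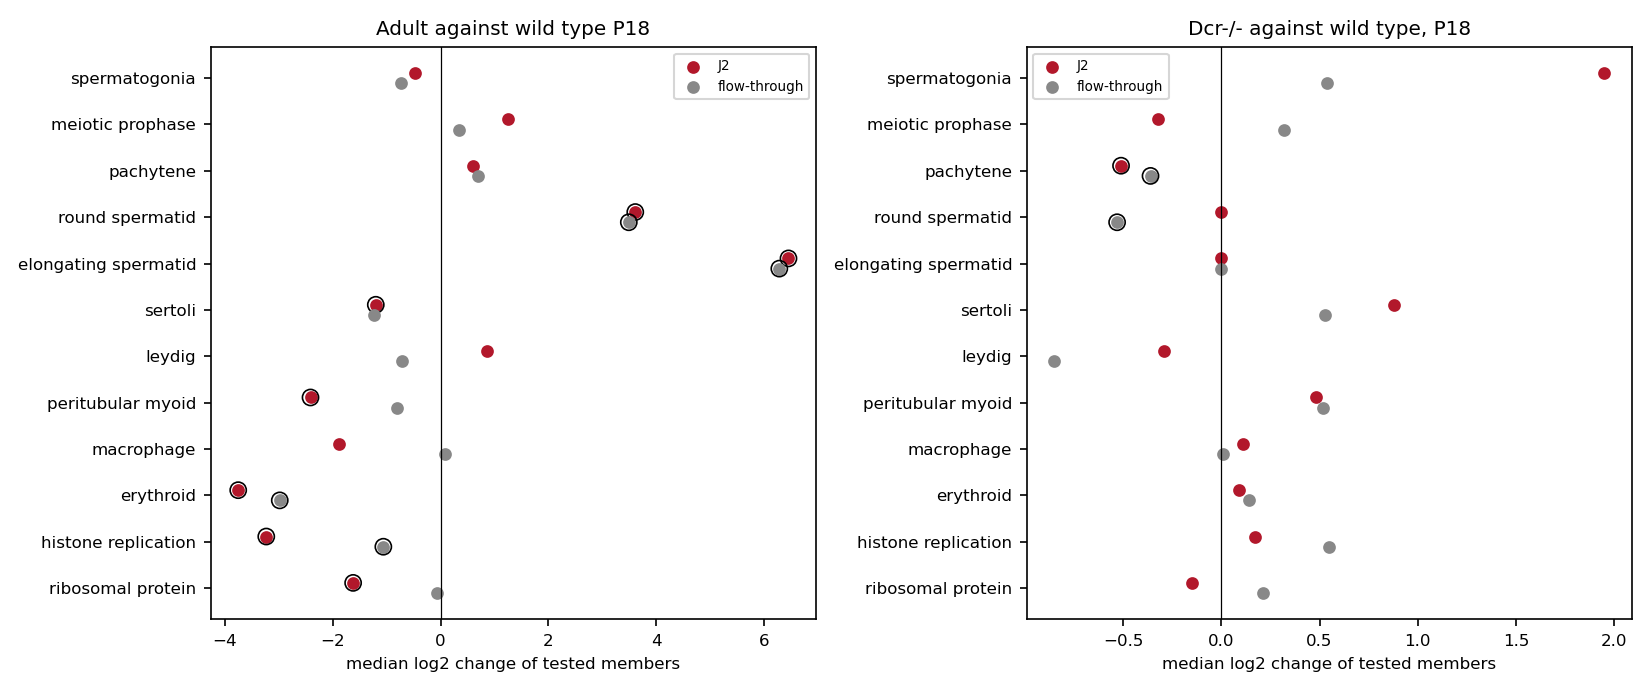
Median log2 change of the tested members of 12 gene lists for adult against wild-type P18 testis (left) and for knock-out (Dcr-/-) against wild type at P18 (right), in J2 and flow-through; encircled points had a camera adjusted p under the threshold of 0.05, and the horizontal scales differ. Elongating spermatid genes lay at 6.45 in J2 and 6.28 in flow-through for age, and pachytene genes at -0.51 and -0.36 for genotype.

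With limma, 349 genes rose and 27 fell in adult J2 (6882 tested), and 220 rose and 11 fell in adult flow-through (7141 tested). The filter needs 2 libraries, the size of the adult group. Genes at 0 in all P18 libraries, such as Oaz3 and Hmgb4, thus entered through their adult values. The surplus of rises is therefore partly fixed by the filter. Of the 22 elongating spermatid genes, 20 were tested in J2 and 19 in flow-through, so the filter left out few of them. Of the genes tested in both fractions, 127 rose in both (205 in J2 and 157 in flow-through, 6.2 for independent lists), 3 fell in both (0.055) and 0 moved in opposite directions. The J2 and flow-through libraries share their codes, so the fractions are not independent and the numbers for independent lists are only a reference. The falls in J2 numbered 12 without P18 J2 replicate 2. Those in flow-through numbered 4 and 6 without P18 flow-through replicates 1 and 3 and 23 without adult replicate 2. Without a filter on low values all 4 counts were 0 (Prm1 adjusted p = 0.069 in J2 and 0.072 in flow-through). The elongating and round spermatid lists were called whichever library was left out, but round spermatid genes in J2 not with a filter at 50 (1.71, adjusted p = 0.09). That filter also ended the J2 calls of respiratory chain (-1.13, 0.054), Sertoli (-1.44, 0.09), peritubular myoid (-2.41, 0.092) and small nucleolar RNA lists (-1.70, 0.09). With only the groups compared the heavy-strand (1.88, 0.1) and light-strand (2.41, 0.1) calls ended, as they did without a filter for the former (1.93, 0.17) and after rescaling for the latter (2.47, 0.051). The Col3a1 call in J2 ended without P18 replicate 1 (-5.24) or 2 (-5.78) or either adult library (-4.84 and -6.85). In flow-through it ended without either adult library (-5.77 and -6.00), as did that of Col1a1 (-4.94 and -6.15). That of Col6a3 ended without adult flow-through replicate 2 (-4.14). In J2 that of Col1a1 ended without P18 replicates 1 and 3 or either adult library (-5.02, -4.76, -6.05 and -4.16), and that of Col1a2 without P18 replicate 2 or adult replicate 1 (-4.27 and -3.63). Without adult J2 replicate 2 the J2 medians were -0.02 (heavy-strand mRNAs, adjusted p = 0.9), 0.52 (light-strand and rRNA list, 0.64), -0.36 (respiratory chain, 0.44), -0.98 (Sertoli, 0.44), -1.86 (peritubular myoid, 0.19), -3.59 (red blood cells, 0.06) and 0.36 (small nucleolar RNAs, 0.65), none of them called. The calls also ended without P18 J2 replicate 1 for the heavy-strand mRNAs (1.35, 0.15), the light-strand list (2.57, 0.061) and Sertoli genes (-1.01, 0.076). They ended without replicate 2 for small nucleolar RNAs (-0.43, 0.15) and without replicate 3 for the light-strand list (2.14, 0.081).

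For age by fraction, limma called 0 of 9526 genes (514 at an unadjusted p under 0.05, smallest adjusted p 0.18). There were 54 higher without adult flow-through replicate 2 and 18 higher and 12 lower without adult J2 replicate 2. After rescaling to a common total 356 were higher and 3 lower. As lists, ribosomal protein mRNAs (median -1.50, camera adjusted p = 8.8e-12, but adjusted p = 0.084 with an estimated correlation) and replication-dependent histones (-2.17, adjusted p = 2.5e-14, but adjusted p = 0.36 with an estimated correlation) had a lower J2 to flow-through difference in adults than at P18. Both list calls held whichever library was left out (-2.07 to -1.10 and -2.74 to -1.18).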

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

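The results in this part were picked by rules set before the data were examined, but the tests on adult J2 replicate 2 were chosen after its values were seen.

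A difference between groups picked 6 gene lists, whose J2 to flow-through difference was not the same in adult and wild-type P18 testis (age by fraction, camera). The adjusted p was 2.5e-14 for replication-dependent histones (median -2.17), 8.8e-12 for ribosomal protein mRNAs (-1.50), 0.00092 for heavy-strand mitochondrial mRNAs (1.93), 0.00098 for the light-strand mRNA with the rRNAs (2.55), 0.014 for small nucleolar RNAs (-0.52) and 0.025 for respiratory chain subunits (-1.35). With an estimated correlation these became 0.36, 0.084, 0.63, 0.22, 0.66 and 0.22. Without adult J2 replicate 2 the medians of the last 4 lists were 0.06, 0.65, -0.61 and -0.84 (adjusted p = 0.72, 0.21, 0.96 and 0.86). None of these 4 was called then. Other settings ended these calls too. Without wild-type flow-through replicate 2 respiratory chain subunits were at -0.70 (camera adjusted p = 0.073) and small nucleolar RNAs at -0.52 (0.19). Leaving out wild-type J2 replicate 2 gave -1.19 (0.092) and -0.64 (0.21). After rescaling to a common total heavy-strand mRNAs were at 2.50 (0.073) and the light-strand list at 3.19 (0.065).

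Tmem147, a membrane protein gene, was picked because its J2 minus flow-through change had opposite directions in wild-type P18 and adult testis, which is not a test. Its value was -4.53 for wild type minus adult, and the interaction test gave an adjusted p of 0.74. Wild-type P18 flow-through had 21.8, 20.4 and 25.8 and J2 0, 0.268 and 1.83. Adult flow-through had 16.2 and 7.17 and J2 25.8 and 10.8.

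Adult J2 replicate 2 stood apart from the other J2 libraries, with values above 0 for 22683 genes, 4666 of them in no other library and 4237 at multiples of 1 read (16 to 94 in the other libraries), and with a mitochondrial share of 10.8%. Thinned to the depth of the next deepest J2 library it would still show 21656 genes, against at most 11591 in any other J2 library, which argues against depth as the reason. Its mitochondrial RNA beyond that of replicate 1 had an mt-Co1 share of 77% of heavy-strand mRNA, whereas flow-through libraries reached at most 21.4%. This argues against carried-over flow-through RNA as the only source of its excess mRNA. Most other heavy-strand mRNAs reached adult flow-through values, such as mt-Nd4 (686 against 24.4 in replicate 1, with 250 and 1160 in flow-through) and mt-Cytb (600 against 43, with 161 and 360). In contrast, mt-Nd1 stayed below them (543, with 884 and 1800). Carry-over of a part is therefore not excluded. The mt-Rnr2 of adult J2 replicate 2 (26900 against 1940 in replicate 1), carried over from adult flow-through, would bring at least 124000 of Mir6236, which was at 90. Mir6236 was low in every J2 library (0.0106% to 0.0427% of the signal, against 2.42% to 7.76% in flow-through). A step that lowers it in all J2 libraries would hide carry-over, so this test cannot decide the question for the rRNA. Other reasons, such as DNA in the library or a different sample, could not be tested with these files.

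Ribosomal protein mRNAs were higher in J2 at P18, and genes of their level could be missed in the shallow flow-through libraries. Their median lay at percentile 100 of random lists of 82 genes with the same mean values (random median 0.2, 95% of lists between -0.27 and 0.64), which argues against that. The families used for the next test were picked after this pattern was seen. In 107 genes of other families of short mRNAs the median was 1.23, also at percentile 100 (random median -0.16, 95% of lists between -0.63 and 0.3). A preference of the J2 libraries for short mRNAs therefore stays open, and the change may not reflect double-stranded RNA.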

How the results depend on the processing

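Of the alternative settings, the filter at 50 and the block by shared code were chosen after the results were seen. Leaving out libraries aside, called lists kept direction and side of the threshold in 238 of the alternative results and lost the call in 36, and named called genes kept both in 724, lost the call in 202 and reversed in 8. With a library left out, the same counts were 188 and 41 for lists and 438, 243 and 0 for called genes. Uncalled named genes turned direction in 61 results and kept direction and side of the threshold in 438. Their remaining results crossed the threshold, with 4 gaining a call and 11 losing one. Genes were sorted here by a rounded adjusted p. The 11 thus come from genes called just under 0.05 that were counted as uncalled, and the split into called and uncalled genes is approximate. When 1 adult library remains, the fit assumes that it varies like the other groups. The planned count test was not run. Unless stated, the cause was not tested.

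Numbers of called genes moved as follows. Wild-type J2 rises (50) became 22 without a filter, 2562 after rescaling to a common total, 23 with only the groups compared, 93 with a filter at 50 and 7 with the block; falls (36) became 20, 13, 24, 60 and 17. Knock-out rises (16) became 25 with a pseudocount of 5, 8 without a filter, 2848 after rescaling, 42 after quantile normalization, 41 with only the groups compared, 33 with a filter at 50 and 4 with the block. Adult rises (14) became 30, 195, 3460, 26, 0, 2 and 2 in the same order, and falls (16) became 56 without a filter. Knock-out against wild type in J2 had 1 fall with only the groups compared, 1 fall with a filter at 50 and 1 rise with all 16 libraries. Adult against P18 rises in J2 (349) became 0 without a filter and 72 with a filter at 50, and falls (27) 0 without a filter, 48 after quantile normalization, 12 with only the groups compared and 49 with all 16 libraries. In flow-through rises (220) became 0 without a filter and 41 with a filter at 50, and falls (11) 0 without a filter, 5 after rescaling, 19 after quantile normalization, 4 with only the groups compared, 7 with all 16 libraries and 6 with a filter at 50. Age by fraction gave 97 rises and 13 falls without a filter, and 356 and 3 after rescaling. The filters change which genes are tested. The rescaling multiplies all values of a library alike, but on log2(value + 1) it moves low genes less than high ones.

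Called lists with an estimated correlation fell in number from 6 to 3 (wild-type J2 against flow-through), 5 to 0 (knock-out), 1 to 0 (adult), 2 to 0 (knock-out against wild type, J2), 2 to 0 (flow-through), 11 to 2 (adult against P18, J2), 4 to 1 (flow-through) and 6 to 0 (age by fraction).

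With each library left out in turn, wild-type rises ran from 10 to 40 and falls from 15 to 43, knock-out rises from 4 to 14 and falls from 15 to 19, and adult rises from 7 to 74 and falls from 11 to 44. Knock-out against wild type stayed at 0. Adult against P18 rises ran from 304 to 322 in J2 and 150 to 219 in flow-through, and falls from 12 to 25 and 4 to 23. Age by fraction ran from 0 to 54 rises and 0 to 12 falls. The mitochondrial share difference ran from -1.23 to -0.373 points (wild-type J2 minus flow-through), -1.94 to -0.402 (knock-out), 0.177 to 9.77 (adult), -0.0349 to 0.169 and -0.367 to 1.17 (knock-out minus wild type, J2 and flow-through), and 0.237 to 9.83 and -1.17 to -0.312 (adult minus P18). Without the 10 highest other genes it was -39.2, -44.8, -24.8, 0.89, 6.44 and -5.79, for the first 5 comparisons and adult minus P18 in flow-through. For adult minus P18 in J2 it went from 5.04 to 8.59 points.

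After rescaling to a common total the median of all genes was 1.87 in wild type, 2.16 in the knock-out and 2.74 in adults for J2 against flow-through. High genes moved further than that median. In wild type all genes went from -0.05 to 1.87, but the light-strand and rRNA list from -5.45 to -1.49. A change of sign can therefore come from the rescaling itself, and these medians do not give its size for high genes. Reversed values after that rescaling were, for J2 against flow-through, in wild type mt-Nd1 0.95, mt-Nd2 0.60, mt-Co2 1.40, mt-Atp6 1.67, mt-Co3 2.58, mt-Nd5 3.26 and mt-Nd6 2.72. In the knock-out they were Dicer1 0.39, mt-Nd1 1.51, mt-Nd2 1.84, mt-Atp6 1.74, mt-Co3 2.31, mt-Nd4 2.05, mt-Nd5 4.04 and mt-Cytb 1.51. In adults they were mt-Rnr1 0.75, Itpr3os 0.31, mt-Nd1 2.42, mt-Nd2 2.60, mt-Atp8 2.82, mt-Atp6 3.44, mt-Co3 4.34, mt-Nd4 2.52 and mt-Cytb 3.96. For knock-out against wild type they were mt-Nd1 -0.18 and mt-Co3 -0.01 in J2, and mt-Nd2 -0.58, mt-Co1 -0.38, mt-Nd4 -0.26, mt-Nd5 -0.15 and mt-Nd6 -0.27 in flow-through. For adult against P18 in flow-through they were mt-Nd2 -0.05 and mt-Nd5 -0.51. Quantile normalization reversed Lars2 in wild type (1.51), Lars2 0.70, mt-Rnr2 0.80 and mt-Rnr1 0.77 in the knock-out, mt-Rnr1 1.49 and mt-Co3 0.25 in adults, mt-Nd1 0.12 for knock-out against wild type in flow-through, and mt-Nd1 0.01 and mt-Nd5 -0.18 for adult against P18 in flow-through. A pseudocount of 5 reversed mt-Nd4l (0.21) for knock-out against wild type in J2.

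Uncalled genes whose direction turned with a library left out had these lowest and highest values. In wild-type J2 against flow-through they were Dicer1 -0.88 to 1.33 and mt-Co2 -3.53 to 0.49. In the knock-out they were mt-Nd3 -0.44 to 2.15 and mt-Nd5 -0.50 to 0.31. In adults they were Dicer1 -1.15 to 2.73, mt-Co2 -1.23 to 6.99, mt-Nd4l -3.35 to 4.28, mt-Co3 -1.61 to 1.16, mt-Cytb -2.46 to 1.31, mt-Atp8 -3.86 to 0.65, mt-Atp6 -2.93 to 0.72, mt-Nd4 -4.41 to 0.35 and mt-Nd5 -1.17 to 1.74. For knock-out against wild type in J2 they were mt-Co2 -0.88 to 2.99, mt-Nd1 -0.23 to 0.48, mt-Nd4l -1.62 to 0.69 and mt-Atp8 -0.74 to 0.91. For knock-out against wild type in flow-through they were mt-Nd6 -0.25 to 0.56, mt-Nd1 -0.37 to 0.30, mt-Nd2 -0.32 to 0.44 and mt-Nd4l -1.90 to 2.62. For adult against P18 in J2 they were Dicer1 -2.29 to 1.59, mt-Co2 -0.52 to 4.57, mt-Nd3 -1.77 to 2.62, mt-Nd1 -0.19 to 1.71, mt-Atp8 -0.70 to 3.81, mt-Nd5 -0.47 to 2.45 and mt-Nd4l -1.13 to 6.44. For adult against P18 in flow-through they were mt-Nd5 -0.30 to 0.47, mt-Nd4l -4.38 to 3.25, mt-Nd1 -0.58 to 0.44, mt-Co3 -1.53 to 1.23, mt-Co1 -1.44 to 0.93, mt-Co2 -6.95 to 1.27, mt-Nd2 -0.25 to 1.32, mt-Nd4 -0.31 to 1.90 and mt-Nd6 -0.86 to 0.17.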

Other observations

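The shares of mt-Co1 and mt-Nd6 were picked and tested after they were seen, and the splits of libraries were planned.

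Shares of mitochondrial mRNA were compared between J2 and flow-through, and since these mRNAs were picked for their shares, their p-values restate what was seen and are adjusted over 2 mRNAs only. The cytochrome oxidase mRNA mt-Co1 made up 62% ± 8.58 of heavy-strand mRNA in J2 and 16.2% ± 3.32 in flow-through (SD, n = 8 libraries each), higher in J2 in 8 of 8 codes (difference 45.7 ± 9.26, exact sign-flip p = 0.0078, the smallest possible, adjusted p = 0.016). Few reads could give uncertain shares, but the highest upper 95% limit in flow-through was 25.2% and the lowest lower limit in J2 50.6%. This argues against counting error alone, as the limits treat approximate reads as independent and cover no other error. The light-strand mRNA mt-Nd6 made up 2.8% ± 2.24 of mitochondrial mRNA in J2 and 0.865% ± 0.441 in flow-through (higher in 6 of 8 codes, exact sign-flip p = 0.031, adjusted p = 0.031). Both codes with a lower J2 share were wild type, where J2 had 0.778%, 0.916% and 1.28% and flow-through 0.964%, 0.988% and 0.636%. The J2 values were 3.76%, 1.97% and 6.04% in the knock-out and 6.15% and 1.46% in adults.

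Libraries were regrouped in all 10 splits of 3 against 3, too few for a p under 0.05. For J2 against flow-through in wild type, 1 split (the real one, 86 genes) reached the real count of called genes (highest other 2) and 1 that of lists (real 6, highest other 4). In the knock-out these were 1 (34 genes, highest other 0) and 2 (5 lists, highest other 5). In each genotype only 4 of the 10 splits part every pair of libraries with a shared code. Among those 4 the highest other counts were 2 genes and 3 lists in wild type and 0 and 5 in the knock-out. For knock-out against wild type 5 splits reached the real 2 lists, in J2 and in flow-through alike (highest other 3 lists). Where the real count was 0, as for genes there and for genes and lists in genotype by fraction, all 10 splits reach it by definition, so these counts carry no information.

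Lists without a call for J2 against flow-through had these medians in wild type, knock-out and adult: mitochondrial RNA turnover 0, -0.29 and -0.48; small RNA biogenesis -1.39, -0.20 and 0.08. Sensing of double-stranded RNA had -0.10, 1.11 and -0.75. Binding or editing of double-stranded RNA had -0.61, 0.14 and 0, interferon-stimulated genes 1.15, -0.79 and 0.35, and the piRNA pathway 0.13, -0.31 and 0.48. Spermatogonia had -0.85, 0.86 and 0.34, meiotic prophase -0.38, -0.78 and 0.40, pachytene spermatocytes 0.35, 0 and 0.05, round spermatids -0.22, 0 and 0.51, and elongating spermatids 0, 0 and -0.05. Sertoli cells had 0.48, 0.87 and 0.60, peritubular myoid cells 0.09, -1.69 and -1.95, red blood cells -0.34, 0.34 and -0.02, Leydig cells 0.52, 0.20 and 0.65, and macrophages -0.03, -0.37 and -0.30. Endothelium had -0.47, 0.39 and 0.75, the Speer family 0.40, 2.30 and 0.49, and imprinted noncoding RNAs 0.47, -0.69 and 0.29. Histones in the knock-out had 0.17, and in adults respiratory chain subunits had 0.82 and the light-strand mRNA with the rRNAs -3.17. Opposite-strand RNAs had 0.42, 0.62 and 0.67 and their host genes -0.18, -0.08 and 0.33. The lists with 2 measured members, not tested, had -0.13, -0.26 and 1.27 (multicopy sex chromosome genes), 1.15, 0.75 and 2.18 (Rhox) and -1.15, 0.66 and -0.06 (immediate-early genes).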
